A study of Mus musculus with 9 samples.

How the data were processed

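Total RNA was isolated from serum with TRIzol, ligated to adapters, copied to cDNA, amplified, selected for size on a gel and sequenced on an Illumina NextSeq 500 with a kit for tRNA fragments, per the labels' protocols. FastQC, cutadapt, Bowtie and edgeR, and the mouse build mm10, are named in the submitters' processing notes, with no versions or roles. Adapter settings and alignment options are not given in the sources used here. Each deposited file is an alignment list of 1 library, in which identical reads were collapsed. The read count of each sequence stands inside its read name, beside its rank among all sequences of the library. A test of the files showed alignments to the forward strand of mature and precursor tRNA references with at most 1 mismatch, for reads of 14 to 40 bases. The files hold only reads that aligned to tRNAs, so the totals are not the depth of the whole libraries.

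The 3 groups of 3 libraries were taken from the treatment labels and the replicate numbers from the titles. The deposited counts were used as they stand, each read counted once however many references it met. A fragment is a distinct read sequence, and 41240 were seen. Each was assigned to the families (amino acid and anticodon) it aligned to, and a name such as Gly-CCC/Gly-GCC means that the read aligns to both and cannot be split between them. Such shared reads made up 24.1% of all. Fragments were classed as 5′ (starting at the first base), 3′ (reaching the CCA tail), internal, or leader, trailer and body of precursors. No genome was used, so positions are those on the tRNA references. Within each group, libraries differed by more than sampling noise, with chi-square per degree of freedom from 3.19 to 52.9, so that none is a mere resampling of another's reads. This does not tell separate animals from separate preparations of 1 sample.

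The planned quasi-likelihood count test was not used for any result here, because the counts stand inside read names and not in a column of counts. The tests used here take the same counts, so their place in the files does not bar the planned test. A side run of it, made to check the scaling factors, was left out. The plan named limma on log2 values as the fallback. limma-voom (limma 3.58.1, R 4.3.3) was taken instead, a choice made after the files were seen and before any test was run. The fallback, on log2 of reads scaled to the median depth plus a pseudocount of 1, was added as an alternative after the main results were seen. The main test used 1 fit over all 9 libraries and two-sided tests adjusted by Benjamini and Hochberg at 0.05. Scaling by trimmed means of M values and the expression filter were computed from their definitions. The filter kept sequences at or above the equivalent of 10 reads at the median depth (44415 reads) in at least 3 libraries, with at least 15 reads in all. It left 733 fragments, 77 of 239 families and 166 of 608 sums of 1 origin within 1 family. Scaling factors ran from 0.471 (SalB replicate 2) to 1.21. In data simulated with 200 changed fragments of 733, the procedure recovered 69%, 85% and 76% of 4-fold changes for high fat diet against normal diet, SalB against high fat diet and SalB against normal diet. It recovered 35%, 27% and 28% of 2-fold changes, and 3.70%, 0.885% and 0.952% of the calls were false.

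Lists were tested with camera (preset correlation 0.01), with camera using an estimated correlation and with fry, which asks whether a list's members move on balance 1 way. The lists, the list tests, the alternatives and the rule for named fragments were fixed before the data were examined. Of 15 lists, 5 of microRNAs could not be tested because the references hold tRNAs, and the oligoguanine 5′ list had fewer than the 5 tested members required. Its most abundant member, the Ala-AGC fragment GGGGAATTAGCTCAAA, had a log2 fold change of 0.63 with SalB against high fat diet and was not called (limma-voom adjusted p = 0.276). The tested lists share members, hold nuclear tRNAs only except for the mitochondrial list, and the precursor list holds leaders and trailers but not precursor bodies. The rule named, per comparison and direction, up to 12 called fragments with the largest fold change and no overlap between groups, or the 5 smallest p where fewer qualified. It added up to 12 called families per direction or the 3 smallest p, the 10 most abundant fragments and the 2 most abundant members of each list. Shares of reads were compared by exact permutation over 280 partitions. Confidence intervals of read ratios are at 95%, and a count of 0 was set to a floor of 3 reads over the group.

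Alternatives were RLE size factors, total counts, no filter, a stricter filter (10 reads in at least 6 libraries), only the libraries compared, the replicate number as a block, a restriction to 16 to 40 bases, reads of 1 family only, mismatch variants merged by position, unadjusted p with a 1.5-fold change, and each library left out in turn. A moderated quasi-Poisson test, limma on log2 values, library quality weights and the removal of Leu-CAG-3-1 precursor reads were chosen after seeing the data. Checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.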

Results

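Small RNA fragments derived from transfer RNAs (tRNAs) were sequenced from mouse blood serum at week 20 in a study of atherosclerosis and salvianolic acid B (SalB), a phenolic compound of the root of Salvia miltiorrhiza. Mice on a normal diet, on a high fat diet, and on a high fat diet with SalB gave 3 libraries each, 9 in all. Reads on tRNA references numbered 43007, 31058 and 94724 in normal diet replicates 1, 2 and 3. The high fat diet libraries held 55465, 28191 and 44415 reads, and the SalB libraries 62258, 156333 and 40134. Of 41240 distinct sequences, 733 were abundant enough to be tested. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples, which may be technical. The labels of the normal diet libraries carry a strain name that those of the other groups do not. The strain of the other groups is not given in the sources used here, so both comparisons with normal diet may mix diet or treatment with strain. Levels below are normalised CPM, given as mean ± SD with n = 3. Positions count from 1 at the 5′ end of the tRNA reference, and precursor references start 40 bases ahead of the mature 5′ end. A substitution such as A56T gives the reference base, its position and the base read.

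The make-up of the libraries was compared first. Fragments of mitochondrial tRNAs made up 3.69 ± 0.591% of the reads on normal diet, 3.97 ± 0.487% on high fat diet and 15.2 ± 5.52% with SalB (n = 3 each). Fragments ending at the 3′ end of a tRNA took 43.6 ± 3.33%, 42.8 ± 2.67% and 24.6 ± 9.59%. Trailers of precursor tRNAs took 5.64 ± 0.926%, 5.24 ± 0.463% and 26.2 ± 19.3%, where SalB replicate 2 alone stood at 47.9%. SalB replicates 1 and 3 stood at 19.4% and 11.2%. Reads on the Leu-CAG-3-1 precursor made up 42.0% of the tRNA reads of SalB replicate 2. Of these, 0% started within 2 bases of the first base after the mature part, which argues against trailers cut there. All shares given here include these reads, which lower the mitochondrial and 3′ shares of that library. Fragments of 5′ ends took 19.4 ± 5.26%, 15.6 ± 2.82% and 17.0 ± 1.13%. None of the 19 measures passed the exact permutation test over all 280 partitions of the libraries, with p = 0.0179 for the mitochondrial share and a smallest adjusted p of 0.0969. For the mitochondrial, 3′ and trailer shares the SalB libraries all lay on 1 side of the high fat diet libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Rank correlations of fragment levels across fragments, which are not independent replicates, ran from 0.695 to 0.815 between normal and high fat diet libraries. They ran from 0.709 to 0.773 among the SalB libraries, and from 0.267 to 0.441 between SalB and all other libraries.

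**Figure D1:**
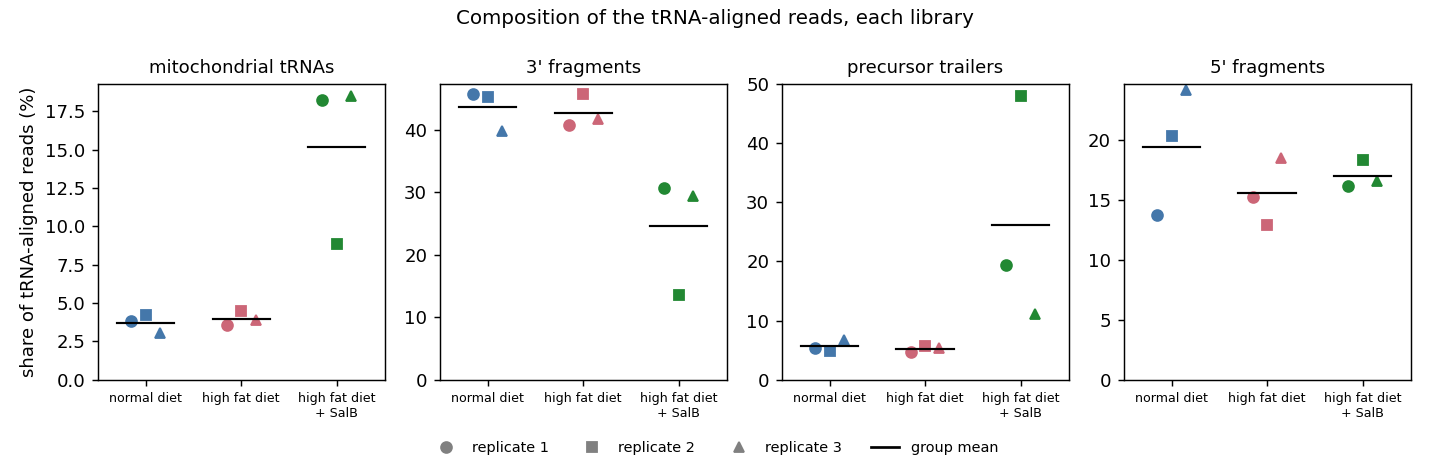
Shares of the tRNA-aligned reads of each library, in percent, for mitochondrial tRNAs, 3′ fragments, precursor trailers and 5′ fragments. Each point is 1 library and each line a group mean. The mitochondrial share lay between 8.83% and 18.5% in the SalB libraries and below all of them in the other libraries.

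The comparison of high fat diet with normal diet asks which serum fragments differ between the diets. No fragment of the 733 passed (limma-voom, Benjamini-Hochberg adjusted p under 0.05). The smallest adjusted p was 0.175, 87 fragments had an unadjusted p under 0.05 where 36.65 would be met by chance, and a moderated quasi-Poisson test and limma on log2 values also called 0. The fragments with the smallest p are therefore given by value alone. The Gly-CCC/Gly-GCC 3′ fragment TCGATTCCCGGCCAATGCACTA (C73T) had a level of 269 ± 216 on normal diet and 928 ± 263 on high fat diet (limma-voom log2 fold change 2.46, SE 0.50, adjusted p = 0.175). The Ala-AGC fragment GGGATTAGCTCAAA (positions 3 to 16) stood at 1631 ± 416 and 4046 ± 478 (log2 fold change 1.34, SE 0.30). The mitochondrial Ser-GCT 5′ fragment AAGAAAGATTGCAAGAACTG stood at 552 ± 559.8 and 1727 ± 155 (2.31, SE 0.56). For the Met-CAT fragment TAATCTGAAGGTCCTGAGG (T54G), 3 reads on normal diet and 32 on high fat diet gave a ratio of 13.7, with a 95% counting interval from 4.28 to 69.8. The Gly-ACC/Val-AAC/Val-CAC fragment GTTTCCGTAGTGTAA (G15A) had a log2 fold change of 1.58 (SE 0.38). In the other direction, the Asp-GTC 5′ fragment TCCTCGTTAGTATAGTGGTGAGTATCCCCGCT (C32T) stood at 924 ± 78.6 and 269.9 ± 72.7 (-1.83, SE 0.43). The long Pro 5′ fragment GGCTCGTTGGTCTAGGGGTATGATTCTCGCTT had a log2 fold change of -2.65 (SE 0.70). The Gly-GCC 5′ fragment GCATTGGTGGTTCAGTGGTAGAATTCTCGT (C30T) stood at 1772 ± 611 and 503 ± 135 (-1.70, SE 0.45). The substitutions T54G, G15A, C32T and C30T lie at the last base of their reads. At the last base, the mismatch share was 16.8 ± 1.01% on normal diet and 19.1 ± 0.965% on high fat diet. At other bases apart from the T-loop A it was 0.623% and 0.730%. Whether these sequences are misread ends of other fragments was not tested. Groups did not overlap for 177 fragments (24.1%), against 10% by chance. With no filter on low counts, TCGATTCCCGGCCAATGCACTA, AAGAAAGATTGCAAGAACTG, TAATCTGAAGGTCCTGAGG, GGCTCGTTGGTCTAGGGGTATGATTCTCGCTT and GCATTGGTGGTTCAGTGGTAGAATTCTCGT passed (limma-voom adjusted p = 0.0441, 0.00589, 0.00126, 0.00167 and 0.0110), and under other settings their adjusted p reached 0.643 (0.572 for TAATCTGAAGGTCCTGAGG).

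Summed over tRNA families, none of 77 passed with limma-voom, 4 had an unadjusted p under 0.05, and the quasi-Poisson test and limma on log2 values called 0. These tests all pool the spread over the 9 libraries, SalB included, so they are not independent of one another. With limma-voom on only the 2 groups compared, 6 of 74 families passed, 3 higher and 3 lower on high fat diet. Lys-CTT/Lys-TTT came nearest, at 812 ± 58.4 and 1442 ± 304 (limma-voom log2 fold change 0.81, SE 0.23, adjusted p = 0.439). Leu-AAG/Leu-TAG had a log2 fold change of -0.59 (SE 0.28). Of 166 sums of 1 origin within 1 family, only the internal fragments of Ala-AGC passed. They rose from 2379 ± 218 to 5887 ± 1070.2 (limma-voom log2 fold change 1.29, SE 0.23, adjusted p = 0.0351). No sum passed with total counts, without a filter, with the stricter filter, with the replicate block, with quasi-Poisson or with limma on log2 values. None passed when any library other than SalB replicate 2 was left out.

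Of the 9 fixed lists tested, 2 were called by camera with a preset correlation of 0.01. The list named serum 5′ fragments holds the 5′ fragments of tRNAs known to give such fragments in serum, among them Gly-GCC, Glu-CTC and Val-CAC. Membership rests on the tRNA and not on a known serum level of each fragment. It holds 116 of the 126 nuclear 5′ fragments tested, so it stands for nearly that whole class. This list was shifted down, with a median log2 fold change of -0.41 (adjusted p = 1.85e-05). The list of 268 internal fragments was shifted up, with a median of 0.24 (adjusted p = 0.000146). Both calls were lost with an estimated correlation, each at adjusted p = 0.340, and with fry (adjusted p = 0.548 and 0.241). No member of either list passed, over all fragments or adjusted over the list alone. The other 7 lists had adjusted p from 0.138 to 0.898. The fry test called only the Met and selenocysteine list (higher, adjusted p = 0.00730). Adjusted over the list alone, 1 fragment of the 14 of Met and selenocysteine tRNAs rose, TAATCTGAAGGTCCTGAGG, whose substitution lies at its last base.

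The comparison of SalB with high fat diet asks which fragments differ after the intervention. The list of mitochondrial tRNA fragments was higher and that of nuclear 3′ fragments lower, both also with an estimated correlation, while the higher level of the list of precursor leaders and trailers was lost with it. All of these calls held with fry (adjusted p = 0.000139, 0.000206 and 0.000977). With limma-voom, 129 fragments rose and 122 fell of 733 tested, 332 had an unadjusted p under 0.05, and the quasi-Poisson test called 205 and limma on log2 values 282. Of the 251 calls, 243 had no overlap between the groups' libraries. Over all fragments 367 did not overlap (50.1%), against 10% by chance. The scaling sets the split: with total counts in place of trimmed means, 66 rose and 237 fell, as the median of all fragments moved by -0.69 on the log2 scale. Directions below are relative to the trimmed-mean scaling.

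Among the called fragments, those of mitochondrial His-GTG had the largest rises. The long 3′ fragment of mitochondrial His-GTG, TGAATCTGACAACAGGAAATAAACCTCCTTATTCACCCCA (positions 32 to 71), rose from 1094 ± 258 on high fat diet to 74285 ± 12379 with SalB (limma-voom log2 fold change 6.06, SE 0.28, adjusted p = 7.26e-08). Its last-base variants A71G, A71T and A71C rose by 7.13, 5.79 and 5.40 on the log2 scale, and the C68A variant by 6.05. The 5′ fragment of mitochondrial Ser-GCT, AAGAAAGATTGCAAGAACT (positions 1 to 19), rose from 795 ± 195 to 14551 ± 8867 (limma-voom log2 fold change 4.07, SE 0.51, adjusted p = 0.000254). By origin, 8 of 10 mitochondrial 3′ fragments, 23 of 31 mitochondrial 5′ fragments and 10 of 13 mitochondrial trailers rose, and 0 fell. Of the whole list of 59 mitochondrial fragments, 43 rose, 0 fell and 16 were not called (48 and 0 adjusted over the list alone). Its median log2 fold change was 1.90 (camera adjusted p = 2.00e-19, and adjusted p = 0.0207 with an estimated correlation). The members are not independent, since several are variants of the same mitochondrial His-GTG fragment. Of 12 mitochondrial families with at least 10 reads per library on average, 4 rose and 0 fell, with a median log2 fold change of 0.31. The rise was thus not shared by all mitochondrial tRNAs.

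Among nuclear precursors, the trailer of Arg-ACG-1-3, TTGGGACTGGTACTCCTTTATT (positions 114 to 135), rose from 10944 ± 1299 to 49105 ± 13762 (limma-voom log2 fold change 2.14, SE 0.29, adjusted p = 0.000476). Its longer form TTGGGACTGGTACTCCTTTATTC (T136C) rose by 4.43 (SE 0.89). The precursor list holds leaders and trailers only: of its 40 fragments, 19 rose, 0 fell and 21 were not called (20 and 0 adjusted over the list alone). Outside it, 0 of 4 precursor body fragments rose and 2 fell, the Gly-GCC fragments TCGTTTCCCGGCCAATGCACA (-2.80) and TCGTTTCCCGGCCAATGCACT (-2.46), named after their values were seen. Apart from their last base, both of these Gly-GCC fragments match the start of the substituted Gly-CCC/Gly-GCC 3′ fragment described below. On mature references they would exceed the limit of 1 mismatch, so they may come from mature tRNA. This was not tested. The median of the precursor list was 1.62 (camera adjusted p = 2.34e-08, lost at adjusted p = 0.1004 with an estimated correlation, kept with fry at adjusted p = 0.000977). The most abundant fragment of all, GGGCTGGAGAGATGGC on the Leu-CAG-3-1 precursor (positions 137 to 152), did not pass. Its level was 7.51 ± 13.0 on high fat diet and 301816 ± 500183 with SalB (limma-voom log2 fold change 9.16, SE 5.54, adjusted p = 0.213), nearly all of it from SalB replicate 2. It passed under 6 settings, among them no filter, total counts, the replicate block and limma on log2 values, with adjusted p from 2.94e-87 to 0.896 over all settings.

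The nuclear 3′ fragments went the other way, with 1 up, 64 down and 171 not called of 236 (0 and 61 adjusted over the list alone). The 1 that rose, named after its value was seen, was the Ser-GCT fragment TCGAATCCCATCCTCGTCGCA (1.27). The median of the list was -0.80 (camera adjusted p = 5.65e-13, and adjusted p = 0.00944 with an estimated correlation). The Gly-CCC/Gly-GCC fragment TCGTTTCCCGGCCAATGCACCA (A56T, positions 53 to 74) fell from 24979.8 ± 4449 to 3598 ± 911 (limma-voom log2 fold change -2.81, SE 0.39, adjusted p = 0.000500). The same fragment without the substitution, TCGATTCCCGGCCAATGCACCA, stood at 39165 ± 7492 and 24989.9 ± 5398 and was not called (limma-voom adjusted p = 0.105). The Ala-AGC fragment TCCCCAGCATCTCCACCA fell from 8116 ± 1567 to 840.5 ± 368 (limma-voom log2 fold change -3.38, SE 0.38, adjusted p = 0.000162), and the Ala-CGC/Ala-TGC fragment TCCCCGGCATCTCCACCA from 20262 ± 1552 to 6526 ± 2328. The Tyr-GTA fragment TCCGGCTCGAAGGACCA fell from 9628 ± 1219 to 1409.9 ± 1582 (limma-voom log2 fold change -3.31, SE 0.58, adjusted p = 0.00199). Its variant TCCGGCTCGAAGGCCCA (A73C) had 43 reads on high fat diet and 0 with SalB, at least 14.8-fold lower at a floor of 3 reads over the group. The Ala-AGC variant GCCCCAGCATCTCCACCA (T58G) had 44 and 1 reads, a ratio of 45.3 with a 95% interval from 7.71 to 1829. Intervals and floors cover counting error only. Of the reads of 3′ fragments, those starting 1 base after an A of the T-loop made up 25.9 ± 1.97% on high fat diet and 16.1 ± 3.22% with SalB, and those holding that A 49.4 ± 2.89% and 68.7 ± 6.36% (n = 3, exact permutation p = 0.1 each, the smallest possible). The Leu-AAG/Leu-TAG fragment CTCCCACCGCTGCCACCA (A68C) fell by 3.91 and the Gln-CTG fragment CTCTCGGTGGAACCTCCA (A58C) by 3.87 on the log2 scale. The log2 fold change of the first was -2.01 (SE 1.04) without SalB replicate 2 and -5.03 (SE 1.84) without SalB replicate 3. The call of the first was lost under 10 settings and that of the second under 6, with adjusted p up to 0.223 and 0.184. That of GCCCCAGCATCTCCACCA was lost without SalB replicate 1 and with quasi-Poisson, and that of TCCGGCTCGAAGGCCCA with quasi-Poisson (each up to adjusted p = 0.116). The libraries whose removal ended a call (adjusted p) were normal diet replicate 2 (0.0510), high fat diet replicate 1 (0.0840), high fat diet replicate 2 (0.0804), high fat diet replicate 3 (0.0884), SalB replicate 1 (0.0745), SalB replicate 2 (0.151) and SalB replicate 3 (0.0628) for CTCCCACCGCTGCCACCA, high fat diet replicate 1 (0.0530), high fat diet replicate 2 (0.0723), high fat diet replicate 3 (0.0722), SalB replicate 1 (0.184) and SalB replicate 2 (0.0687) for CTCTCGGTGGAACCTCCA, and SalB replicate 1 (0.0748) for GCCCCAGCATCTCCACCA.

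Nuclear 5′ fragments moved both ways, with 23 up, 14 down and 89 not called of 126. The Gly-GCC fragment GCATTGGTGGTTCAGT (positions 1 to 16) rose from 65.9 ± 21.7 to 3372 ± 2107 (limma-voom log2 fold change 5.22, SE 0.81, adjusted p = 0.00110). For GCATTGGTGGTTCA, which Gly-CCC shares, 2 reads on high fat diet and 101 with SalB gave a ratio of 49.1 (95% interval 13.2 to 411). The longer Gly-GCC fragment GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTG (positions 1 to 33) fell from 9223 ± 5079 to 2734 ± 348 (limma-voom log2 fold change -1.59, SE 0.52, adjusted p = 0.0347). That call was lost under 7 settings (adjusted p up to 0.115), among them the removal of normal diet replicate 2 (0.0503), high fat diet replicate 1 (0.115), high fat diet replicate 3 (0.109), SalB replicate 1 (0.0698) and SalB replicate 3 (0.0868), while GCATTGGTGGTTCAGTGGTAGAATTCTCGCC stood at 11383 and 11899 and was not called. Nor was the sum of all Gly-GCC 5′ fragments (log2 fold change 0.27, limma-voom adjusted p = 0.637). The list of serum 5′ fragments had 23 up, 14 down and 79 not called of 116 (22 and 14 adjusted over the list alone), with no call by camera (adjusted p = 0.388).

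Internal fragments of nuclear tRNAs had 43 up, 42 down and 183 not called of 268 (41 and 39 adjusted over the list alone; camera adjusted p = 0.781, median 0.10, mean -0.08). Among those that fell, the Gln-CTG/Gln-TTG fragment TGGTTAGCACTCTGG went from 564 ± 115 to 32.9 ± 35.7 (limma-voom log2 fold change -3.82, SE 0.68, adjusted p = 0.00213), and the Pro fragment GGTATGATTCTCGC fell with a log2 fold change of -1.01 (SE 0.36). The latter call was lost under 11 settings (adjusted p up to 0.167), among them the removal of normal diet replicate 3 (0.0555), high fat diet replicate 1 (0.0925), high fat diet replicate 2 (0.0913), high fat diet replicate 3 (0.0871), SalB replicate 1 (0.167) and SalB replicate 2 (0.0926). For the Val-AAC/Val-CAC fragment TTCCGTAGTGTAGTGGTTATCACGTTCGCC, 40 and 3 reads gave a ratio of 13.7 (95% interval 4.37 to 69.3). The nuclear tRNAs whose anticodon can carry queuosine, a base taken up from diet and gut microbes, had 8 up, 24 down and 59 not called of 91 (10 and 26 adjusted over the list alone). Mitochondrial His-GTG, which rose as a family, is not on this list. The median of the nuclear queuosine list was -0.75 (camera adjusted p = 0.00987, lost at adjusted p = 0.1004 with an estimated correlation, kept with fry at adjusted p = 0.00101). Fragments of tRNAs for branched-chain amino acids had 4 up and 13 down of 74 (3 and 10 adjusted over the list alone; camera adjusted p = 0.0555). Targets of the cytosine methyltransferase Dnmt2 had 37 up and 35 down of 207, the same counts adjusted over the list alone (adjusted p = 0.832). Met and selenocysteine tRNAs had 3 up and 0 down of 14, the same adjusted over the list alone (camera adjusted p = 0.0555). That list was called as higher by fry (adjusted p = 0.000216), but not by camera with either correlation. With total-count scaling the median turned negative for the serum 5′ fragments (-0.56), the internal fragments (-0.70) and the Met and selenocysteine list (-0.09).

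At the level of families, 9 rose and 15 fell of 77 (limma-voom), 35 had an unadjusted p under 0.05, the quasi-Poisson test called 23 and limma on log2 values 20. All 24 had no overlap between libraries, as did 46.8% of the families tested. Mitochondrial His-GTG rose from 5909.6 ± 399 to 89468 ± 29557 (limma-voom log2 fold change 3.85, SE 0.32, adjusted p = 2.02e-05). Mitochondrial Ser-GCT (1.87), Phe-GAA (1.88), mitochondrial Gly-TCC (1.69), Arg-ACG (1.23) and Ile-TAT (1.06) also rose. Tyr-GTA fell from 28947 ± 3373 to 7927 ± 5518 (limma-voom log2 fold change -2.03, SE 0.38, adjusted p = 0.00440), Ala-CGC/Ala-TGC fell by 1.51 and Gln-CTG fell by 1.05. Arg-CCG/Arg-CCT (-1.81), Gly-CCC (-1.20), Thr-AGT (-1.15) and Leu-AAG/Leu-TAG (-1.10) fell too. Of the 21 families named by the fixed rule, 8 passed under every setting tried. The calls above ended with the removal of high fat diet replicate 1 (0.0514) for Arg-CCG/Arg-CCT, high fat diet replicate 1 (0.0514) and high fat diet replicate 2 (0.0600) for Gly-CCC, normal diet replicate 1 (0.0502), high fat diet replicate 1 (0.0793), high fat diet replicate 2 (0.0902) and high fat diet replicate 3 (0.0859) for Thr-AGT and high fat diet replicate 1 (0.0615), high fat diet replicate 2 (0.0745) and high fat diet replicate 3 (0.0665) for Leu-AAG/Leu-TAG. That of Arg-ACG was lost with total counts (adjusted p = 0.0630, the highest of its settings). Without high fat diet replicate 1 only 10 families passed, and without replicate 3 only 12. Of 166 sums of 1 origin within 1 family, 19 rose and 26 fell. They fell by 2.27 for Tyr-GTA 3′ fragments and by 1.33 for Gly-CCC/Gly-GCC 3′ fragments, while Gly-CCC/Gly-GCC 5′ fragments rose by 2.70. Without SalB replicate 2, which held the Leu-CAG-3-1 reads, 205 of the 251 fragment calls remained.

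**Figure D2:**
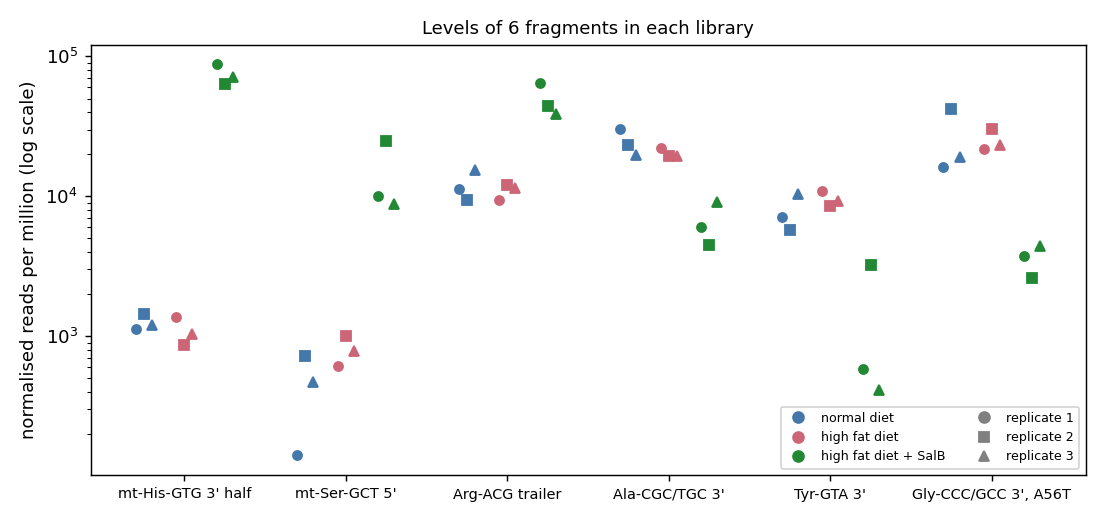
Levels of 6 fragments in each library, in normalised CPM on a log scale, with marker shapes for the replicates and colours for the groups. All SalB libraries lie above the others for the mitochondrial His-GTG 3′ fragment, the mitochondrial Ser-GCT 5′ fragment and the Arg-ACG trailer. They lie below them for the 3′ fragments of Ala and Tyr tRNAs and for the A56T variant of the Gly-CCC/Gly-GCC 3′ fragment. The Gly fragment without the substitution is not drawn.

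The comparison of SalB with normal diet asks how far the treated mice stand from those on normal diet. The picture was close to that against high fat diet. With limma-voom 150 fragments rose and 136 fell of 733, 369 had an unadjusted p under 0.05, and the quasi-Poisson test called 270 and limma on log2 values 302. Of the 286 calls, 273 did not overlap, and 369 fragments (50.3%) did not overlap in all, against 10% by chance. Total-count scaling gave 80 up and 248 down, with a shift of the median of -0.65. The long mitochondrial His-GTG 3′ fragment rose from 1257 ± 171 to 74285 ± 12379 (limma-voom log2 fold change 5.87, SE 0.28, adjusted p = 8.73e-08), and the mitochondrial Ser-GCT fragment AAGAAAGATTGCAAGAACT from 446 ± 293 (limma-voom log2 fold change 5.19, SE 0.56, adjusted p = 6.23e-05). The short Gly-GCC fragment GCATTGGTGGTTCAGT rose by 5.09 (SE 0.74). The Met-CAT fragment TAATCTGAAGGTCCTGAGT rose from 1652 ± 387 to 4725 ± 495 (limma-voom log2 fold change 1.51, SE 0.30, adjusted p = 0.00296), a call lost with total counts at adjusted p = 0.0879, the highest of its settings. Among those that fell, the Pro fragment TGGTCTAGGGGTATGATTCTCGCT went from 894 ± 557 to 37.5 ± 9.73 (limma-voom log2 fold change -3.91, SE 0.83, adjusted p = 0.00416). The Arg-CCT fragment TTGGCTTCCTAAGCCAGGGATTGTGGGT (C32T) went from 1955 ± 710.2 to 214 ± 172 (limma-voom log2 fold change -3.44, SE 0.53, adjusted p = 0.000752). The Gly-CCC 3′ fragment TCGTTTCCCGGGCGGCGCACC (A56T) fell with a log2 fold change of -3.38, and the long Asp-GTC 5′ fragment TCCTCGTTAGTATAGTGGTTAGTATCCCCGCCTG with -3.32. The call of TCGTTTCCCGGGCGGCGCACC was lost with quasi-Poisson at adjusted p = 0.0510, the highest of its settings.

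By origin, 10 of 10 mitochondrial 3′ fragments, 28 of 31 mitochondrial 5′ fragments and 21 of 37 nuclear trailers rose, 1 nuclear trailer fell, and 69 of 236 nuclear 3′ fragments fell and 3 rose: Ala-AGC TCAATCCCCGGCACCTCCACCG (1.25), Ser-GCT TCGAATCCCATCCTCGTCGCA (1.23), Gly-TCC TCGATTCCCGGCCAACGCACCG (1.46) (named after their values were seen). Of the nuclear 3′ fragments that rose, those of Ala-AGC and Gly-TCC end in CCG in place of CCA. The mismatch share at the last base of reads was 16.8 ± 1.01% on normal diet and 22.9 ± 5.59% with SalB. Whether these are misread ends was not tested. The trailer that fell was Ser-GCT TCTGTAGCTTATAAGGTC (-1.56), and of 4 precursor body fragments 0 rose and 1 fell, Gly-GCC TCGTTTCCCGGCCAATGCACT (-2.44). As said above, the latter may come from mature tRNA. Of 77 families, 13 rose and 10 fell (limma-voom, 35 at an unadjusted p under 0.05, 25 by quasi-Poisson, 22 by limma on log2 values). Mitochondrial His-GTG rose by 3.99 (SE 0.32), mitochondrial Ser-GCT by 2.31, Lys-CTT/Lys-TTT by 1.36 and Met-CAT by 1.00. The Met-CAT call was lost with total counts and without normal diet replicate 2 (0.0675) and SalB replicate 1 (0.0513), with adjusted p up to 0.176. Leu-AAG/Leu-TAG (-1.69), Ala-CGC/Ala-TGC (-1.67), Gln-CTG (-1.14) and Tyr-GTA (-1.91) fell. Of 166 sums of 1 origin within 1 family, 32 rose and 21 fell. Without SalB replicate 2, 38 families passed, and 237 of the 286 fragment calls remained.

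Camera called 7 of the 9 lists. The mitochondrial list was higher (49 up, 0 down of 59, and 50 up, 1 down adjusted over the list alone, the latter being mt-Ser-TGA GAGAAAGACATATAGGATATGAGATT (-1.44); adjusted p = 5.68e-19, and adjusted p = 0.0220 with an estimated correlation). The list of nuclear 3′ fragments was lower (2 up and 62 down adjusted over the list alone; adjusted p = 1.11e-13, and adjusted p = 0.0122 with an estimated correlation). The other 5 calls were lost with an estimated correlation. With fry only the internal list of these was lost (adjusted p = 0.0618). The precursor (0.00108), Met and selenocysteine (3.67e-05), queuosine (0.00108) and branched-chain (0.0490) lists passed with fry. Precursor leaders and trailers had 21 up and 1 down of 40, the same adjusted over the list alone (adjusted p = 1.15e-06, lost at adjusted p = 0.106), and internal fragments 62 up and 42 down of 268, also unchanged adjusted over the list alone (adjusted p = 0.0402, lost at adjusted p = 0.316). Met and selenocysteine tRNAs had 7 up and 0 down of 14, the same over the list alone (adjusted p = 0.00940, lost at adjusted p = 0.0744). Branched-chain amino acid tRNAs had 4 up and 13 down of 74 (3 and 10 adjusted over the list alone; adjusted p = 0.00940, lost at adjusted p = 0.278), and nuclear queuosine tRNAs, without mitochondrial His-GTG, 10 up and 31 down of 91, the same over the list alone (adjusted p = 0.0159, lost at adjusted p = 0.106). With total-count scaling the median of the internal list turned negative (-0.40), as did that of the Dnmt2 list (-0.61), which was not called and whose median was 0.01 and mean -0.01. It had 37 up and 34 down of 207 (35 and 32 adjusted over the list alone; adjusted p = 0.722). The serum 5′ fragments were not called either (adjusted p = 0.450, 14 up and 20 down of 116, 11 and 18 adjusted over the list alone).

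The last comparison asks whether SalB turned back what the high fat diet changed. No fragment was called in opposite directions by limma-voom in both comparisons, since none passed for high fat diet against normal diet. At an unadjusted p under 0.05 with at least a 1.5-fold change, 27 fragments met the condition in opposite directions, and the quasi-Poisson test and limma on log2 values gave 0. No number expected by chance was computed for the 27. Sharing the high fat diet libraries yields opposite changes without any effect, so this count cannot be read as reversal. Across the 733 fragments, the fold changes of both comparisons had a correlation of -0.143, against a median of -0.513 (95% of values from -0.574 to -0.429) in 100 simulations of unchanged groups that shared the high fat diet libraries. Their covariance was -0.181, just outside the simulated range (median -0.139, 95% of values from -0.177 to -0.107). The simulated groups held no SalB effect, whereas 251 fragments were called for SalB against high fat diet. The wider spread of such fold changes by itself draws a correlation toward 0 and may widen the range of the covariance. Neither value therefore shows reversal or its absence. Both SalB comparisons shared 111 fragments up and 89 down, where independent lists of these sizes would share 26.4 and 22.6. Simulated unchanged groups shared 0, which was all but fixed beforehand, since groups without an effect yield few calls. That 0 does not measure the overlap that shared libraries alone would give. The covariance of the fold changes of both SalB comparisons was 2.79 against 0.132 simulated, and part of any excess in overlap may come from the shared SalB libraries.

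**Figure D3:**
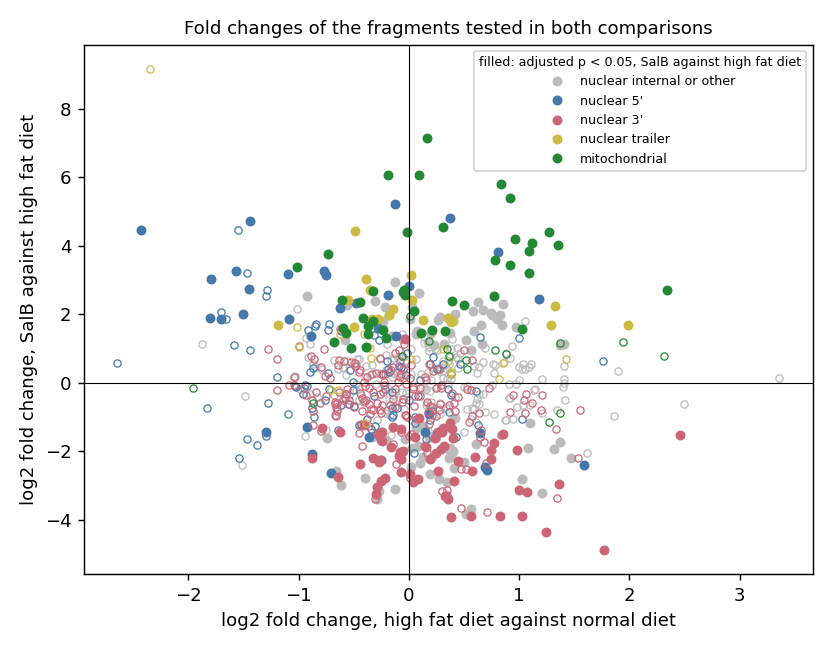
Log2 fold change of each of 733 fragments, high fat diet against normal diet on the horizontal axis and SalB against high fat diet on the vertical axis, coloured by origin. Filled points passed for SalB against high fat diet. Mitochondrial fragments lie above 0 on the vertical axis where filled, and 64 of the 65 filled nuclear 3′ fragments lie below it.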

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

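All tests of the Leu-CAG-3-1 reads below were chosen after the result was seen. The read names rank every distinct sequence of a library, tRNA or not, so the highest rank met gives the least number of distinct sequences. It was 239170 in SalB replicate 1 and 1060429 in SalB replicate 2, above the highest value of 206302 in the normal diet libraries. SalB replicate 3 stood at 159825. The sequences outside tRNAs were not analysed here.

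SalB replicate 2 also held 65630 reads on the precursor of Leu-CAG-3-1, 42.0% of its tRNA reads, against 1588 in SalB replicate 1, 23 in replicate 3, 26 in the high fat diet libraries together, and 15, 6 and 100 in normal diet replicates 1, 2 and 3. Cleavage of a trailer at the mature 3′ end was argued against: 0% of these reads started within 2 bases of the first base after the mature part (position 124), the most frequent start being 137, while nearly 100% of the Arg-ACG trailer reads (99.99%) did. Carry-over from SalB replicate 2 into replicate 1 remains open: of 23 sequences seen almost only in replicate 2, 91.3% were found in replicate 1 at within 2-fold of a median of 2.54% of the replicate 2 count. Of these 23 sequences, 16 lie on this precursor, and the other 7 ran from 1.76% to 3.65%, so a shared source in both libraries cannot be excluded by this test. A candidate source is repeat RNA, since B2 repeats of the mouse genome open with a like sequence, which was not tested because no genome was used; an effect of SalB itself was not tested either.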

How the results depend on the processing

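The quasi-Poisson test, limma on log2 values, the library quality weights and the removal of Leu-CAG-3-1 reads were chosen after seeing the data. The planned negative binomial Wald test was not run, and nor was a count per reference copy. Calls of fragments stayed within 1.5 times of their number under all settings but these. Without a filter 55, 1145 and 1292 fragments passed for high fat diet against normal diet, SalB against high fat diet and SalB against normal diet, of which 10, 253 and 292 were among the 733 and the rest had a median of 19 reads. The stricter filter, which tested 498, gave 164 and 190 for the SalB comparisons, and unadjusted p with a 1.5-fold change gave 87 for high fat diet against normal diet. With each library left out in turn, fragments ran from 191 to 298 and 221 to 353 in the SalB comparisons and stayed at 0 in the other.

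Families called for high fat diet against normal diet were 6 with only the 2 groups compared and 4 at unadjusted p. For SalB against high fat diet they ran from 10 (without high fat diet replicate 1) to 31 with a library left out. For SalB against normal diet they were 14 with total counts and ran from 16 to 38 (without SalB replicate 2). Sums by origin for high fat diet against normal diet were 0 with total counts, without a filter, with the stricter filter, with the replicate block, with quasi-Poisson and with limma on log2 values, 3 with only the 2 groups, 15 at unadjusted p, and 0 to 1 with a library left out. For SalB against high fat diet they were 29 with only the 2 groups and 29 with quasi-Poisson, and ran from 20 (without high fat diet replicate 1 or 3; 23 without replicate 2) to 51. Fragments called in opposite directions were 17 without a filter and 27 at unadjusted p. Lists called for high fat diet against normal diet were 0 with an estimated correlation, 1 with fry, and 1 to 3 with a library left out (1 without normal diet replicate 3). In each SalB comparison 2 lists were called with an estimated correlation, and more with fry. The cause of these changes was not tested, except that no filter and the stricter filter test more and fewer fragments.

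The replicate numbers are shared between groups, but same-numbered libraries did not deviate together (correlations from -0.319 to 0.149), and not every library correlated best with its own number. They share only a number. With the replicate block, 0, 264 and 271 fragments, 0, 18 and 19 families and 0, 37 and 52 sums by origin passed.

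Of 28 called fragments named by change or level for SalB against high fat diet, 19 passed under every setting, and of 29 for SalB against normal diet, 22. Of 21 and 22 families, 8 and 11 did. Among the named fragments, 23 values of log2 fold change in 9 combinations of fragment and comparison took the other sign, none with adjusted p under 0.05, and the cause was not tested. For high fat diet against normal diet, TCGTTTCCCGGCCAATGCACCA (0.09 in the main analysis) was -0.0548 without a filter (-0.21 to 0.43 with a library left out), TAGAATTCTCGCCTGCCACG (0.11) was -0.0345 without a filter (-0.00812 to 0.16), TTGGGACTGGTACTCCTTTATT (-0.15) ran from -0.33 to 0.0779, and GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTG (-0.37) from -0.80 to 0.15. For SalB against high fat diet, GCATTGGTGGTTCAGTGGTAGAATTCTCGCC (-0.07) was 0.0811 with quasi-Poisson (-0.83 to 0.30), TAGAATTCTCGCCTGCCACG (-0.15) ran from -0.51 to 0.0356, and GGGGAATTAGCTCAAA (0.63) was -0.0654 with total counts. For SalB against normal diet, TAGAATTCTCGCCTGCCACG (-0.04) was 0.0165 with RLE, 0.11 with quasi-Poisson and 0.0494 at 16 to 40 bases (-0.41 to 0.15), and TTTAGTAGTACCGTCCCTTT (0.37) was -0.18 with total counts (-0.00141 to 0.59).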

Other observations

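The tests of the T-loop, of mitochondrial RNA from cells, of separate preparation and of the calls ended by the removal of length and GC trends were chosen only after the result was seen, and so was the reading of the bound for length and GC content. Among 12 mitochondrial tRNA families with at least 10 reads per library on average, 4 rose with SalB against high fat diet and 0 fell (limma-voom): mitochondrial His-GTG, Ser-GCT, Gly-TCC and Thr-TGT, the last with 19 reads on high fat diet. Its call (adjusted p = 0.0386) was lost under 9 settings (adjusted p up to 0.213), among them the removal of normal diet replicate 3 (0.0552), high fat diet replicate 1 (0.169), high fat diet replicate 3 (0.120) and SalB replicate 1 (0.0680). The median log2 fold change of the 12 was 0.31. Mitochondrial Val-TAC (0.88, SE 0.35) and mitochondrial Glu-TTC (-0.36, SE 0.28) were not called. Among sums of 1 origin, Trp-CCA internal fragments rose by 2.51 and Phe-GAA internal fragments by 2.26 with SalB against high fat diet, and Glu-TTC 3′ fragments fell by 1.77.

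Reads over an A of the T-loop, 18 bases before the end of the tRNA, carried another base in 21.1 ± 6.70% of cases on normal diet, 17.7 ± 2.67% on high fat diet and 3.00 ± 0.980% with SalB (n = 3, exact permutation p = 0.1 for SalB against high fat diet, the smallest possible). This base is often methylated (1-methyladenosine), which makes reverse transcriptase misread it. Of 19 tRNA families with at least 30 such reads per library, only 5 had a mismatch share over 5% on high fat diet. They were Gly-CCC, Gly-CCC/Gly-GCC, Gly-GCC, Gly-TCC and Tyr-GTA, and in all 5 every SalB library lay below every high fat diet library. The other families lay under 5% and their means moved both ways. Among them, every SalB library also lay below every high fat diet library for Ser-GCT, Thr-AGT and Leu-CAG. Their means were 1.11%, 3.54% and 4.06% on high fat diet and 0%, 1.01% and 1.21% with SalB. For iMet-CAT every SalB library lay above (0.22% on high fat diet and 1.30% with SalB). For Tyr-GTA, SalB replicate 2 (14.7%) lay above normal diet replicates 1 and 3 (9.61% and 12.8%). The fall is thus clearest for Gly tRNAs and not shown for tRNAs at large. A loss of mismatches of every kind was argued against by the ratio of SalB to high fat diet at other bases, 0.957, above the 0.9 set as a bound, with 0.169 at the T-loop A; without the last read base the ratio was 0.818, below that bound, so a smaller general loss is not excluded. A shift between tRNAs was not excluded by a first test, which asked for a lower SalB mean in every family and found it in 13 of 19; in a second, chosen after the first missed its bound, weighting the families as in high fat diet gave 6.57% with SalB against 18.4 ± 1.91%, so that a shift may explain a part but not the whole. Lower methylation of the base with SalB and a difference in reverse transcription between library preparations stay open: that fewer 3′ fragments started 1 base after this A (16.1 ± 3.22% against 25.9 ± 1.97%) and more held it (68.7 ± 6.36% against 49.4 ± 2.89%) goes with either.

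The 251 fragment calls for SalB against high fat diet were weighed as another pattern. Read depth as the whole cause was argued against: with each library thinned to 28191 reads a median of 169.5 fragments passed in 10 draws (158 to 184), of which a median of 156.5 were among the 251, though the bound set, the highest of the other splits, was low at 0. Mitochondrial RNA brought in by cells stays open: the highest and lowest of 12 families, picked for their values, differed by 4.25 on the log2 scale (SE 0.46), which excludes only RNA that raises all families alike, and the profile of such RNA was not measured. Length and GC content as the whole cause were argued against, since 224 calls after removing each library's trend lie above the bound set on the count; read as calls shared with the 251 they were 161, below that bound, and the 90 that ended went from a median log2 fold change of 1.91 (median SE 0.51) to 0.88 (0.48) in the main direction, a ratio of 0.461, so that the trend could account for these. SalB libraries that were prepared apart from the rest cannot be told apart from the treatment, as the nearest SalB library lay 34.3 from the nearest other library on the first principal component (59.5% of the variance) and no label gives a preparation date.

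The 10 splits of 6 libraries are too few for a share under 0.05. For high fat diet against normal diet the real split called 0 fragments and 0 families, as the other splits did at most, so 10 of 10 splits gave as many. It called 1 sum by origin (highest other 0, 1 of 10 splits) and 2 lists (highest other 3, 6 of 10). For SalB against high fat diet it called 251 fragments, 24 families and 45 sums by origin, with a highest other of 0 for each (1 of 10), and 4 lists with a highest other of 6 (9 of 10). For SalB against normal diet it called 286 fragments, 23 families and 53 sums by origin, with a highest other of 0 (1 of 10), and 7 lists with a highest other of 6 (1 of 10).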
